A study of Mus musculus with 12 samples.

How the data were processed

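RNA-seq was done on regulatory T cells (Tregs), sorted by flow cytometry as CD4+CD25hiCD127lo singlets from the mesenteric lymph nodes of SAMP/YitFC mice. Mice were wild type (WT) or lacked estrogen receptor beta (ERb-KO, gene Esr2), and were male or female. Per the labels' protocols, RNA was isolated with the NucleoSpin XS kit, cDNA was made with SMART-Seq v4 and libraries with Nextera XT. That combination does not mark the strand, so reads of overlapping or antisense genes cannot be told apart. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these samples.

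The authors deposited a table of raw counts per gene symbol, with 26609 genes in 12 libraries. Per the submitters' processing notes, the tools were HISAT2 2.0.5, featureCounts 1.5.0-p2, Subread and edgeR, and the genome build was GRCm38. The annotation release and the strand setting are not given in the sources used here. The authors also deposited log2 values for the 24584 genes with a count above 0. Counts scaled to library size (CPM), recomputed with edgeR's trimmed mean of M values (TMM) and a prior count of 0.25, matched those log2 values to within 5e-14. The counts were tested, and the log2 values served in an alternative. Neither table held mitochondrially encoded genes, so that list gave no value here.

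Groups were taken from the sample titles, which gave 4 groups of 3 libraries: WT male, WT female, KO male and KO female. Libraries were numbered within a group. The title numbers did not serve as a block, since nothing in the labels says that they mark a litter or a day. In the WT male group the number 2 occurs on 2 titles. They were kept as separate libraries because the labels list them as separate samples, and whether they share a mouse is not stated. Summing them took the called genes from 10 to 0 in males and from 206 to 31 for the average over the sexes.

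Genes were filtered by filterByExpr, which left 13692 genes and at least 99.8% of the counts of each library. Libraries were scaled by TMM. One edgeR quasi-likelihood model of 4 group means with robust dispersion was fitted to all 12 libraries (R 4.3.3, edgeR 4.0.16), so all groups shared 1 estimate of the spread. The 6 comparisons were KO minus WT in females, in males and averaged over the sexes, female minus male in WT and in KO, and the interaction (the KO effect in females minus that in males). Tests were two-sided. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 29.3%. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM in the text use TMM-scaled library sizes. Total counts are given in M.

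Before the data were examined, lists of genes were fixed for Treg identity and function, helper T cell programs, signalling, metabolism, cell cycle, RNA quality and the other cell types that a lymph node sort can hold. The 33 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over those lists. Within a list, genes were also counted with p adjusted over the list alone. For each list of another cell type, CPM were summed per library and compared on log2(CPM + 1) by a two-sided exact permutation test, adjusted over 12 lists. The smallest p is 0.00216 for 6 against 6 libraries, and for 3 against 3 it is 0.1.

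Named genes followed a rule fixed before the data were examined. Esr2, Esr1, Foxp3, Il2ra, Il7r, Xist and the Y-linked genes were always named. For each pairwise comparison the rule took the 12 largest changes in each direction among passing genes with an average of at least 1 CPM and groups that did not overlap, leaving out provisional gene names and antigen receptor segments, or all passing genes where there were fewer than 5. For the average and the interaction it took the 10 passing genes with the smallest p. For each list it took up to 4 passing members, or, where a called list had none, the 2 with the smallest p. Up to 5 passing genes within 10 Mb of Esr2 completed it. Gene positions came from the RefSeq annotation of GRCm38.p6, which matched 96.6% of the tested genes by symbol. A fold against a group with 0 counts in every library is a lower bound, taken against 3 counts over that group's libraries.

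The steps were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold among 13692. For KO minus WT averaged over the sexes, 68 of the 2-fold and 96 of the 4-fold genes were recovered. In females 44 and 84 were recovered, and in males 51 and 82. For female minus male the numbers were 47 and 82 in WT and 48 and 85 in KO, and for the interaction 17 and 69. Between 4 and 8 unchanged genes were called per comparison. Changed genes averaged at least 1 CPM, and each gene was drawn independently of the others. Real genes varied together, with an estimated correlation of 0.713 for ribosomal protein genes in the average, so these numbers need not hold for the real comparisons.

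Alternatives chosen before the data were examined were scaling by relative log expression, DESeq2 (1.42.0), limma voom with quality weights, no filter on low counts, a filter at 1 CPM in at least 3 libraries, only the groups compared, non-robust dispersion, the title number as a block, WT male 2 and 3 summed, removal of genes on X and Y, and each library left out in turn. Added after seeing the data were removal of the GC and length trend, removal of the 4 libraries whose sex-linked transcripts went against their titles, and removal of the 3 libraries with the lowest mean correlation with the others. Both removals of libraries left a single KO male library, so tests of that group there borrow their spread from the other groups. Also added was limma trend on the log2 values, in place of a planned log2 of the value plus 1, which cannot be taken of negative values.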

Results

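Transcript levels were measured in Tregs from the mesenteric lymph nodes of SAMP/YitFC mice, an inbred line that develops ileitis spontaneously. The design crosses sex with presence or absence of ERb, the estrogen receptor encoded by Esr2, and asks how Tregs of each sex differ with and without it. There were 3 libraries in each of 4 groups. Total counts were 15.8 ± 1.18 M in WT males, 14.5 ± 0.949 M in WT females, 11.98 ± 1.94 M in KO males and 12.5 ± 1.99 M in KO females (mean ± SD, n = 3 each). Single libraries ranged from 10.2 to 16.7 M, so the KO-labelled libraries were on average shallower. A gene with 0 counts could still be present at up to 0.176 CPM in the deepest library and up to 0.291 CPM in the shallowest, which covers counting error only.

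Esr2 (chromosome 12, 76120419 to 76177259, GRCm38.p6) did not follow the labelled genotype. The libraries labelled WT male 1, 2 and 3 held 0, 1 and 14 Esr2 counts, and those labelled WT female 1, 2 and 3 held 0, 133 and 159. The libraries labelled KO male 1, 2 and 3 held 8, 2 and 95 counts, and those labelled KO female 1, 2 and 3 held 161, 94 and 128. Esr2 was thus at most 0.895 CPM in 6 libraries and between 8.05 and 12.3 CPM in the other 6. Of the WT-labelled libraries 4 lay in the low range and 2 in the high range, and of the KO-labelled libraries 2 were low and 4 high. In the test of KO minus WT averaged over the sexes the log2 fold change of Esr2 was 1.93 (SE 1.01, adjusted p = 0.378). The deleted part of the gene is not given in the sources used here, and counts over a whole gene can include transcripts of a disrupted allele.

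Sex-linked transcripts went against the title in 4 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 4639, 5312 and 6591 counts in WT male 1, 2 and 3, to 3313 in KO male 3, to 5501 in the library labelled WT female 2 and to 3987 in the library labelled KO female 1, and those 6 libraries had at most 16 Xist counts. Xist, the RNA of the inactive X chromosome, had 1518 and 1497 counts in WT female 1 and 3, 1378 and 662 in KO female 2 and 3, and 3864 and 1016 in the libraries labelled KO male 1 and KO male 2, with 0 Y-linked counts in all 6. WT female 2, KO female 1, KO male 1 and KO male 2 were therefore opposite to their titles. All groups below are those of the titles, and every direction between sexes or genotypes rests on these labels.

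**Figure D1:**
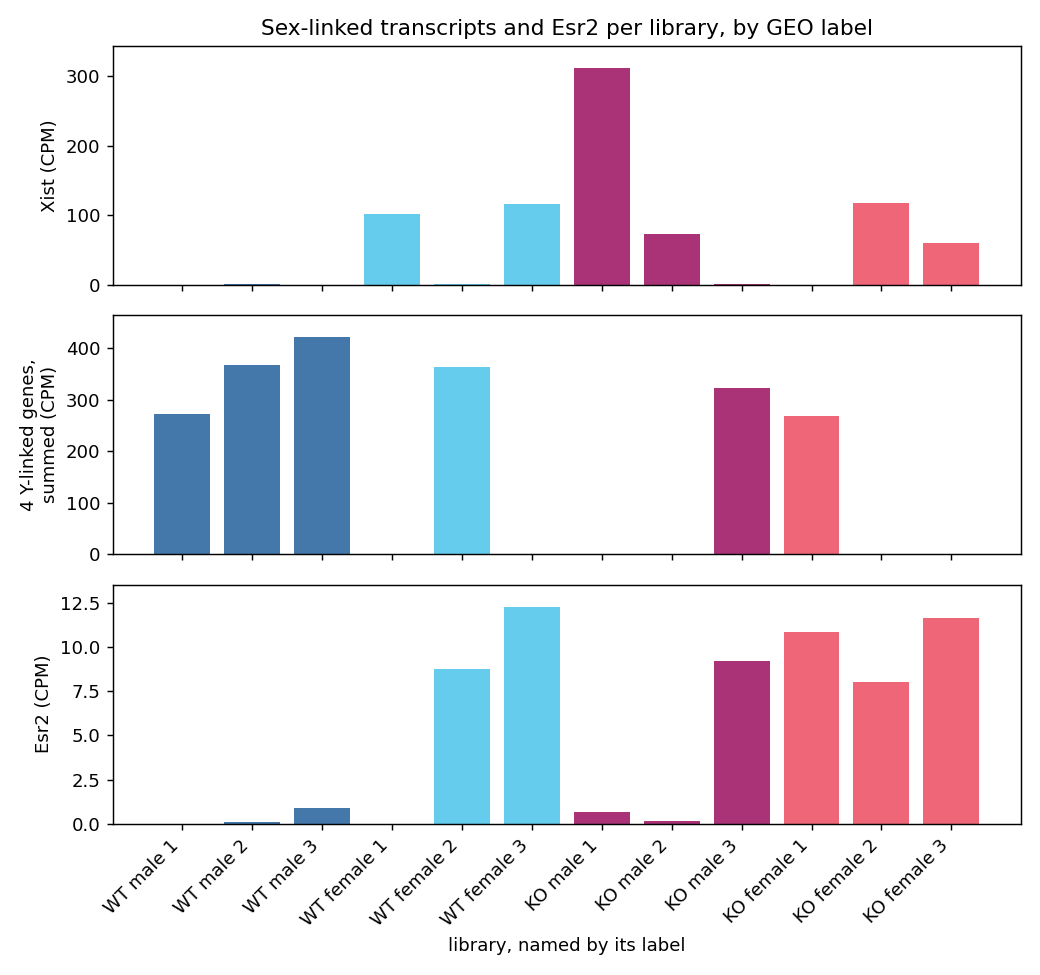
CPM of Xist, the summed CPM of 4 Y-linked genes and the CPM of Esr2 (y axes) in each of the 12 libraries (x axis), with bar colour for the labelled group. Libraries titled WT female 2 and KO female 1 carry Y-linked transcripts, KO male 1 and KO male 2 carry Xist, and Esr2 is at least 8.05 CPM in 4 of the libraries titled KO.

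Foxp3 and the transcripts of 2 surface markers of the sort were measured in every library. Foxp3, the lineage transcription factor of Tregs, averaged 755 ± 122 CPM over the 12 libraries, and Il2ra, which encodes CD25, averaged 788 ± 161 CPM (SD, n = 12). Il7r, which encodes CD127 and is low on the sorted cells, averaged 186 ± 32.8 CPM. None of them passed in any comparison, and neither did Esr1, the other nuclear estrogen receptor gene, at 2.62 ± 1.12 CPM. For KO minus WT averaged over the sexes the log2 fold changes were -0.06 for Foxp3, -0.11 for Il2ra, -0.22 for Il7r and -0.21 for Esr1 (adjusted p = 0.885, 0.817, 0.465 and 0.861).

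Averaged over the sexes, single genes known from B cells and granulocytes were among the 83 that rose in KO-labelled Tregs, and 123 other genes fell. The B-cell surface genes Ms4a1, Cd22 and Cd79a rose by 3.24 (SE 0.48), 2.51 (SE 0.37) and 2.06 (SE 0.37) on the log2 scale. Ms4a1 averaged 29.3 ± 13.5 CPM in the 6 KO-labelled and 5.77 ± 7.08 CPM in the 6 WT-labelled libraries (SD). The granulocyte genes Ngp, S100a9, S100a8 and Lcn2 also rose, from almost no counts. Ngp averaged 3.83 ± 4.36 CPM in KO and 0.01 ± 0.02 CPM in WT. Among genes that fell were Scin, an actin-severing protein (4.03 ± 0.97 against 16.1 ± 4.26 CPM), the fatty acyl-CoA reductase Far1 (79.4 ± 8.07 against 149 ± 14.6 CPM), Sh3bgrl (82.7 ± 19.0 against 159 ± 9.14 CPM) and Dcun1d1 (68.4 ± 9.94 against 112 ± 6.34 CPM), each lower in all 6 KO-labelled libraries than in any WT-labelled library.

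With edgeR, 206 of 13692 genes passed for this average, 83 higher with a median log2 change of 1.45 and 123 lower with a median of -0.60. At an unadjusted p under 0.05 there were 2183. Over all 13692 genes tested, the 6 KO-labelled and 6 WT-labelled libraries did not overlap in 329, or 2.40%, where chance gives 0.216%, and 129 of those 329 passed. The adjusted p was 0.00273 for Scin (chromosome 12, 40059769 to 40134228), 0.00308 for both Far1 (chromosome 7) and Sh3bgrl (X), and 0.0106 for Ms4a1 (chromosome 19). Chst3, a chondroitin sulfotransferase gene, rose by 3.17 (SE 0.44, adjusted p = 0.00828). With limma voom and quality weights 597 passed, of which 205 were higher and 392 lower, and with the title number as a block 9 passed. The count rested on single libraries. It fell to 12 without KO female 3, 23 without WT male 3, 26 without WT female 3, 39 without WT male 2, 46 without WT female 2, 53 without KO female 1, 60 without WT female 1 and 86 without KO male 3, and was 543 without KO male 2. It was 14 without the 4 libraries that went against their titled sex, 34 with the GC and length trend removed, and 605 with DESeq2, of which 329 were higher and 276 lower.

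Some of the genes that rose belong to lists of other cell types. Of 19 tested B-cell genes, 9 were higher over all genes tested and 18 adjusted over the list alone, with a median log2 change of 1.91 (camera adjusted p = 6.7e-33). The adjusted p of the B-cell list was 0.0827 with an estimated correlation and 0.0122 with fry. Summed B-cell CPM were 1407 ± 515 in KO and 554 ± 335 in WT (n = 6 each, exact permutation p = 0.00866, adjusted 0.0519). The dendritic cell list, led by the MHC class II genes Cd74 (1.38), H2-Ab1 (1.61) and H2-DMb2 (1.45), had 3 of 19 members higher, 8 adjusted over the list alone, and a median of 0.83 (adjusted p = 3.8e-09, and adjusted p = 0.148 with an estimated correlation). Its summed CPM were 2251 ± 456 against 1388 ± 313 (exact permutation p = 0.00216, adjusted 0.0260) and did not overlap. Much of that sum came from Ccr7 (915 ± 97.9 in KO and 753 ± 143 CPM in WT) and Cd74 (772 ± 292 and 315 ± 174 CPM). The list therefore does not measure dendritic cells alone. Of its 19 genes 7 stand in another list, with Cd74 and H2-Ab1 in the B-cell list as well, and 8 had at least 1 CPM in every WT library, so its call is not independent of the B-cell genes. The neutrophil and mast cell list had 4 of 14 members higher and 7 adjusted over the list alone, with a median of 2.95 (adjusted p = 4.4e-07, and adjusted p = 0.0978 with an estimated correlation), and summed to 59.2 ± 19.3 against 39.1 ± 10.5 CPM (adjusted exact p = 0.0557). Of the 14 neutrophil and mast cell genes 12 were positive, but the most abundant, Kit and Mmp9, were lower without passing. Kit averaged 15.2 ± 7.44 CPM in KO and 21.1 ± 4.48 CPM in WT, and Mmp9 9.81 ± 3.52 and 11.8 ± 2.86 CPM. Only 2 of the 14 had at least 1 CPM in every WT library. Fitted fold changes of genes with so few counts depend on the prior count.

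Further lists of other cells were called upward with the preset correlation and lost with an estimated one. The macrophage and monocyte list had a median of 1.25, with Ly6c2 higher by 1.97, 10 of 19 members higher adjusted over the list alone and adjusted p = 0.148 with an estimated correlation. Reads of Ly6c2 and of its near-identical neighbour Ly6c1 may be split between them by the counting. The plasma cell list (median 0.54, adjusted p = 0.186 with an estimated correlation) held 2010001M09Rik, now named Mzb1, which rose by 4.35 (SE 0.67), and Prdm1, which fell by 0.78. Medians were 1.29 for stromal and endothelial genes (Cxcl13 3.86, Dcn 3.20), 1.46 for thymocyte genes (Cd8b1 0.68, Cd24a 1.68) and 0.67 for CD8 and NK cell genes (Cd8b1, Tyrobp 1.49), and none of the genes named for these 3 lists passed. Their adjusted p were 0.148, 0.148 and 0.403 with an estimated correlation, and the CD8 and NK cell call was lost without KO female 3 (0.0826). Summed CPM in KO and WT were 837 ± 137 and 684 ± 166 for the macrophage and monocyte list, 700.5 ± 116 and 579 ± 40.5 for plasma cell, 154 ± 28.1 and 115 ± 18.8 for stromal and endothelial, 96.2 ± 22.96 and 63.6 ± 16.8 for thymocyte and 110.3 ± 27.1 and 80.1 ± 16.6 for CD8 and NK cell genes, with adjusted exact p between 0.0519 and 0.118. Single members made up much of the first sums. In KO and WT, Ctss averaged 400 ± 74.2 and 375 ± 37.0 CPM in the macrophage list and Xbp1 391 ± 29.6 and 380 ± 27.8 CPM in the plasma cell list. Pecam1 averaged 134 ± 18.2 and 106 ± 17.6 CPM in the stromal list, and Themis 52.6 ± 15.6 and 42.8 ± 12.7 CPM in the thymocyte list. The sums are therefore no measure of the amount of such cells.

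Among lists of T cell biology, genes of resting lymph node T cells were higher in KO-labelled libraries. Their median was 0.29, with 20 of 22 members positive, 3 passing over all genes and 9 adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.0827 with an estimated correlation). The passing members were Igfbp4 (2.00, SE 0.40), Ly6c1 (1.07, SE 0.18) and the transcription factor Lef1 (0.59, SE 0.12). Igfbp4 also stands in the lists of estrogen receptors and cofactors and of conventional CD4 T cells, neither of which was called. The Th17 list was lower (median -0.35, 3 of 17 positive, adjusted p = 0.00409, and adjusted p = 0.2501 with an estimated correlation), with Il1r1 at -0.61 and Ahr at -0.45, neither of which passed. Cytosolic ribosomal protein genes had a median of 0.18 (Rpl12 0.34, Rpl13a 0.33) and cell cycle genes of 0.22 (E2f2 0.52, Cenpf 0.99), with no passing member and adjusted p = 0.960 and 0.929 with an estimated correlation. The ribosomal list lost its call without KO male 1 or WT male 3 (adjusted p = 0.175 and 0.118) and without the 4 libraries that went against their titled sex (0.726), and the cell cycle list without KO male 2, WT female 3 or WT male 3 (0.234, 0.399 and 0.0959).

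Other passing list members fell. Gbp1, a guanylate-binding protein gene of a multigene family on chromosome 3, dropped by 0.68, the repressor Prdm1 by 0.78, and the Notch pathway genes Adam10 and Rbpj by 0.75 and 0.68. Zfx, the X copy of a pair of X and Y genes, dropped by 0.84. Hif1a, a hypoxia-inducible transcription factor, dropped by 0.60 (SE 0.12, adjusted p = 0.0312). The tested lists that hold these genes were not called apart from the plasma cell list. The list of X copies of Y-linked genes, which holds Zfx, was not tested as a list. In all, 21 of 33 lists were not called: Treg core, effector Treg, Th1, Th2, Tfh and Tfr, gut homing, IL-2 STAT5 response, TGF-beta response, estrogen receptors and cofactors, interferon response, NF-kB response, T cell receptor signalling, Notch signalling, apoptosis, glycolysis, cholesterol synthesis, fatty acid oxidation, unfolded protein response, nuclear respiratory chain, immediate early and heat shock, and conventional CD4 T cell. Their medians lay between -0.14 for effector Treg and 0.18 for Notch signalling. The epithelial and the erythroid and platelet lists had only 4 tested genes each (medians -0.10 and 0.49).

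**Figure D2:**
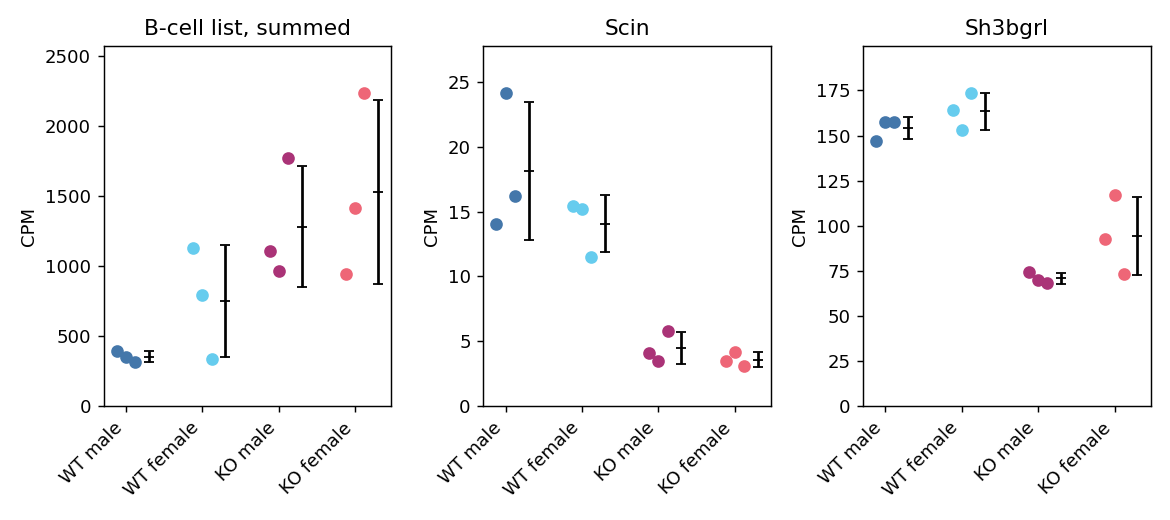
CPM (y axes) of the summed B-cell list, Scin and Sh3bgrl in the 4 labelled groups (x axis), with points for single libraries and a black bar for the mean ± SD (n = 3). Scin is at most 5.82 CPM in the KO-labelled and at least 11.5 CPM in the WT-labelled libraries, while the B-cell sums overlap between WT female and KO libraries.

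Genes near Esr2 were not called more often than others. Of 145 tested genes within 10 Mb, 1 passed in the average (Hif1a, chromosome 12, 73901324 to 73947554), against 200 of 13083 elsewhere (odds ratio 0.447, 95% interval 0.011 to 2.56, Fisher's exact p = 0.729). Since Esr2 itself did not follow the labels, this does not say where a knockout allele was carried.

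In males, the B-cell genes Ms4a1 and Cd22 rose in KO-labelled libraries. Ms4a1 averaged 27.4 ± 16.2 against 0.87 ± 0.78 CPM and Cd22 38.1 ± 13.4 against 2.19 ± 0.59 CPM (SD, n = 3). Log2 fold changes were 4.93 for Ms4a1 and 4.11 for Cd22 (SE 0.75 and 0.57, adjusted p = 0.0234 and 0.0216). Also higher were 2010001M09Rik (6.01), the myeloid receptor gene Lilrb3 (5.79), Chst3 (4.70), the lysosomal protease gene Ctsh (3.68) and Arhgap29 (2.56). Lower were Scin (-2.02, SE 0.31) and Sh3bgrl (-1.12, SE 0.17). With edgeR 10 genes passed, 8 higher and 2 lower, with 1947 at an unadjusted p under 0.05. KO male 1 and KO male 2 are the libraries with Xist and no Y-linked counts. No gene passed without any 1 of WT male 1, WT male 2, WT male 3, KO male 1 or KO male 3, while 734 passed without KO male 2 and 49 without WT female 3, and the count was 5 without WT female 2 and 6 without either KO female 2 or KO female 3. It was 403 with DESeq2, 0 with WT male 2 and 3 summed, 0 with limma voom and quality weights, and 135 without the 4 libraries that went against their titled sex.

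Of 33 lists, 12 were called in males, and none held with an estimated correlation. The summed CPM of 3 of the 12 overlapped between KO and WT males. The B-cell list had 16 of 19 members higher adjusted over the list alone, against 3 over all genes, and a median of 2.75 (adjusted p = 0.176 with an estimated correlation). Summed B-cell CPM were 1283 ± 431 in KO and 353 ± 38.4 in WT males (exact permutation p = 0.1, the smallest possible). Macrophage and monocyte genes had a median of 1.82 (Apoe 2.29, Csf1r 3.42), dendritic cell genes of 1.55 (Cd74 1.78, H2-Ab1 2.01), stromal and endothelial genes of 1.52 (Cxcl13 5.37, Pecam1 0.54), thymocyte genes of 1.22 (Cd24a 1.93, Themis 0.71), plasma cell genes of 1.38 and resting T cell genes of 0.36 (Il6ra 0.98, Lef1 0.69). The neutrophil and mast cell median was 4.29 fitted and 3.64 with its 3 genes at 0 in WT males set to their lower bound. S100a9 was at least 54.6-fold higher by that bound (adjusted p = 0.0929), 23.9-fold without KO male 3 and 34.9-fold without WT male 1. Cell cycle genes had a median of 0.45 (Cenpf 2.35, Ube2c 2.18). Called downward were interferon response genes with a median of -0.38 (Ifit2 -0.70, Cmpk2 -1.11), immediate early and heat shock genes with -0.36 (Bag3 -0.82, Btg2 -0.57) and nuclear respiratory chain genes with -0.11 (Atp5h -0.38, Ndufb9 -0.36). Apart from the B-cell genes and 2010001M09Rik, the list members given here did not pass. With an estimated correlation the adjusted p were 0.176 for the macrophage, dendritic, stromal, resting T cell and neutrophil lists, 0.344 for thymocyte, 0.186 for plasma cell, 0.591 for cell cycle, interferon and immediate early, and 0.795 for respiratory chain genes. Calls were lost without KO male 2 for cell cycle, plasma cell and thymocyte genes (adjusted p = 0.0716, 0.0716 and 0.126), without WT male 3 for stromal and endothelial genes (0.0650), and without KO male 3, WT male 1 or WT male 2 for respiratory chain genes (0.959, 0.541 and 0.253). Without the 4 libraries that went against their titled sex the thymocyte and plasma cell calls were lost (0.0645 and 0.0567), and with the title number as a block that of respiratory chain genes (0.153).

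In females, the interferon response list was called upward at the preset correlation only. Of 49 tested members 43 were positive and 16 were higher adjusted over the list alone, with a median of 0.64 (adjusted p = 3.9e-19, and adjusted p = 0.232 with an estimated correlation). Irf7, which encodes an interferon regulatory factor, had a log2 fold change of 1.23 (SE 0.29) and Cmpk2 of 1.40 (SE 0.36), both with adjusted p = 0.459. Summed CPM of the list overlapped, at 9504, 7419 and 9860 in WT female 1, 2 and 3 and 9078, 10468 and 12516 in KO female 1, 2 and 3. The lowest sum was that of WT female 2, and the highest that of KO female 3. No single gene passed with edgeR, where the smallest adjusted p was 0.104, for Ngp. At an unadjusted p under 0.05 there were 1055 genes, and 19 passed with DESeq2, 1698 with limma voom and quality weights, 0 with limma trend, 2 without WT female 3 and 60 without the 3 libraries that correlated least with the others. WT female 2 and KO female 1 are the libraries with Y-linked counts and almost no Xist.

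Of 33 lists, 13 were called in females, and none held with an estimated correlation. The summed CPM of 9 of the 13 overlapped between KO and WT females. B-cell genes had a median of 1.02 (Cd79b 0.72, H2-Ab1 1.21), with 19 of 19 positive and 0 passing over the list alone, and summed to 1531 ± 657 CPM in KO and 754 ± 399 CPM in WT (exact permutation p = 0.2). Neutrophil and mast cell genes had a median of 1.58, with Ngp at least 88.6-fold and Lcn2 at least 18.2-fold above WT females, where they had 0 counts. These bounds, against 3 counts over the group, fell without KO female 3 to 43.4-fold for Ngp and 5.003-fold for Lcn2, without WT female 1 to 57.8-fold and 11.8-fold and without WT female 2 to 57.4-fold and 11.8-fold. Medians were 1.33 for thymocyte genes (Cd8a 1.33, Cd8b1 0.74), 0.51 for macrophage and monocyte genes (Ly6c2 2.02, Ccr2 -0.92), 0.42 for CD8 and NK cell genes, 0.23 for dendritic cell genes (Bst2 0.96), 0.24 for resting T cell genes (Ly6c1 1.51, Klf2 0.66), 0.31 for cytosolic ribosomal protein genes (Rpl12 0.54, Rpl13a 0.47), 0.19 for nuclear respiratory chain genes (Atp5l 0.59, Atp5d 0.49) and 0.26 for immediate early and heat shock genes (Dusp2 0.42, Dusp1 0.80). Th17 genes had a median of -0.49 (Il1r1 -0.85, Ahr -0.70) and gut homing genes of -0.24 (Ccr2, Ccr6 -0.77). None of these genes passed. With an estimated correlation the adjusted p were 0.232 for the B-cell, neutrophil, thymocyte, resting T cell and Th17 lists, 0.258 for gut homing, 0.4998 for CD8 and NK cell, 0.508 for the macrophage, dendritic and ribosomal lists and 0.584 for the respiratory chain and immediate early lists. Calls were lost without WT female 3 for CD8 and NK cell, dendritic cell and macrophage genes (adjusted p = 0.287, 0.718 and 0.538), without KO female 3 for CD8 and NK cell, macrophage and thymocyte genes (0.389, 0.127 and 0.0708), without KO female 2 or WT female 1 for gut homing genes (0.0671 and 0.106), and without KO female 1, WT female 1 or WT female 2 for immediate early genes (0.109, 0.262 and 0.254). The immediate early call was also lost without the 4 libraries that went against their titled sex (0.752) and with the GC and length trend removed (0.0963).

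**Figure D3:**
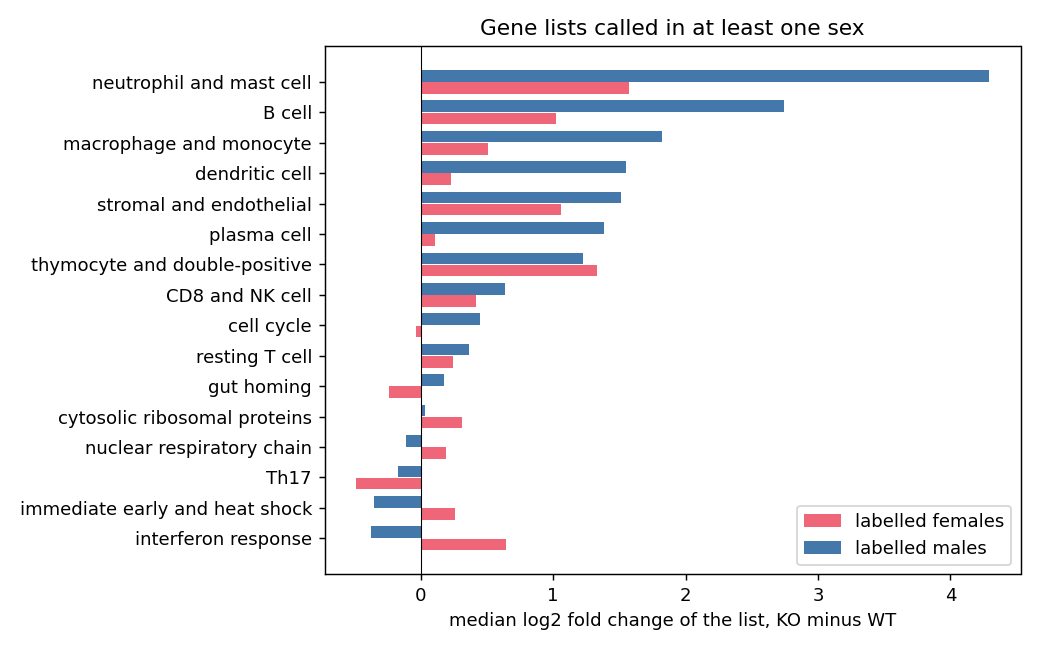
Median log2 fold change, KO minus WT, of each gene list called at the preset correlation in labelled females (red) or labelled males (blue), on the x axis, with lists on the y axis. B-cell genes lie above 0 in both sexes, at 1.02 and 2.75, and interferon response genes lie at 0.64 in females and -0.38 in males.

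The agreement of the KO effect between the sexes was weak across genes, with Pearson's r = 0.266 and Spearman's rho = 0.25002 over 13692 genes, which are not independent replicates. At an unadjusted p under 0.05 in both sexes, 342 genes moved the same way, where independent lists would share 73.0. Of those, 136 were higher and 206 lower. The comparisons share no libraries. Pearson's r was 0.150 without WT male 3, 0.177 without KO female 3 and -0.016 without the 4 libraries that went against their titled sex. The test of the difference itself, the interaction, passed for 0 genes with edgeR, with 659 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma voom and quality weights. It passed for 4 genes without KO male 2 and for 1 without WT female 3.

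At the level of lists, 9 were called for the interaction at the preset correlation and none with an estimated correlation (adjusted p = 0.418 to 0.523 with an estimated correlation). Interferon response genes had the smallest p, with a median interaction of 0.91, 46 of 49 positive and 15 passing over the list alone (adjusted p = 1.3e-30, and adjusted p = 0.418 with an estimated correlation). Cmpk2 (2.52) and Usp18 (1.68) led them without passing over all genes. B-cell genes had a median of -1.25, with 6 of 19 lower over the list alone (Cd22 -3.20, adjusted p = 0.523 with an estimated correlation). Further medians below 0 were -1.08 for macrophage and monocyte genes (Apoe -2.17, Lyz2 -2.87), -0.81 for dendritic cell genes (Fscn1 -3.75, Ccl22 -3.33), -0.57 for cell cycle genes (Cenpf -2.73, Mki67 -1.16) and -0.54 for gut homing genes (Itga4 -0.96, Ccr6 -0.60). Medians above 0 were 0.49 for immediate early and heat shock genes (Nfkbia 0.70, Dusp1 1.51), 0.33 for nuclear respiratory chain genes (Ndufb9 0.52, Ndufs7 0.46) and 0.33 for cytosolic ribosomal protein genes (Rpl5 0.57, Rpl30 0.61). No gene of these lists passed over all genes, and their adjusted p were 0.465 for gut homing and 0.523 for the others with an estimated correlation. Without WT female 2, 14 lists were called. Calls were lost without KO male 2 for cell cycle, gut homing and macrophage genes (adjusted p = 0.0880, 0.0880 and 0.101), without WT female 1 for dendritic cell, gut homing and macrophage genes (0.139, 0.0506 and 0.172), and without WT male 3 for dendritic cell and macrophage genes (0.0613 and 0.107). Those of macrophage, dendritic cell and gut homing genes were also lost without the 4 libraries that went against their titled sex (0.327, 0.264 and 0.0859).

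Between the sexes in WT-labelled libraries no gene passed, and 13 lists were called at the preset correlation. All 13 calls were lost with an estimated correlation (adjusted p = 0.365 for the neutrophil and mast cell list and 0.216 for the others). The summed CPM of all 13 lists overlapped between the titled sexes, which were not uniform. WT female 3 had summed CPM of 1028 for dendritic cell and 560 for macrophage and monocyte genes, below each WT male (1094 to 1430 and 573 to 596), of 336 for B-cell genes, within the WT male range (317 to 393), of 11373 for immediate early and heat shock genes (WT males 11175 to 12571), and of 1621 for cell cycle genes (WT males 1539 to 1722). WT female 1 and 2 had 1736 and 1762, 951 and 834, 1131 and 796, 6054 and 6264, and 2350 and 2235, so for these lists the difference rested on them, and WT female 2 is the library with Y-linked counts. For ribosomal protein and respiratory chain genes the difference rested on WT male 1 and 2 (19043 and 18185, 11000 and 10465), while WT male 3 (12737 and 8536) lay below WT female 2 (13832 and 8903). B-cell genes had a median of 1.51 with 11 of 19 higher over the list alone (Cd22 3.46), macrophage and monocyte genes of 1.40 (Apoe 2.17, Csf1r 3.06), dendritic cell genes of 1.18 (Fscn1 3.96, Flt3 3.52) and cell cycle genes of 0.52 (Mki67 1.08, Kif11 1.38). Cytosolic ribosomal protein genes had a median of -0.47, with 0 of 77 positive (Rpl12 -0.60, Rpl27 -0.58), nuclear respiratory chain genes of -0.34 (Ndufb7 -0.57, Ndufb9 -0.42), interferon response genes of -0.42 (Usp18 -0.95, Cmpk2 -1.21), immediate early and heat shock genes of -0.42 (Dusp1 -1.26, Nfkbia -0.89) and NF-kB response genes of -0.13 (Nfkbia, Ccl22 3.13). Th2 genes (median 0.31, Ccr4 0.45, Epas1 0.78), TGF-beta response genes (0.31, Tgfbr3 1.11, Smurf1 0.65) and estrogen receptors and cofactors (0.25, Esr2 4.42) were called upward, as were neutrophil and mast cell genes (1.28 fitted, 0.86 with genes at 0 in 1 group set to their bound, Retnlg at least 3.32-fold, or 1.83-fold without WT female 1 and 2.12-fold without WT male 1, Mcpt4 3.31). None of these genes passed. Calls were also lost when 1 library was left out: NF-kB without WT female 1 (adjusted p = 0.111), TGF-beta without WT female 3 or WT male 1 (0.0534 and 0.0768), estrogen receptors and cofactors without WT female 3 or WT male 2 (0.0767 and 0.111), Th2 without KO male 2, WT female 1, WT female 3, WT male 2 or WT male 3 (0.0547 to 0.171), and neutrophil and mast cell without KO female 1, KO male 2, KO male 3, WT female 1, WT female 3, WT male 2 or WT male 3 (0.0653 to 0.337). The TGF-beta and the estrogen receptor calls were lost with the GC and length trend removed (0.113 and 0.157), and the Th2 and the neutrophil and mast cell calls with the title number as a block (0.108 each). With edgeR 0 genes passed, 893 had an unadjusted p under 0.05, and DESeq2 gave 33 and limma voom with quality weights 348. The count was 38 without WT female 3, 33 without WT male 3 and 1 without KO female 3. Xist (7.18, adjusted p = 0.718) and the Y-linked Ddx3y (-1.80), Uty (-1.57), Eif2s3y (-1.13) and Kdm5d (-1.09) did not pass, with the library labelled WT female 2 opposite to its group.

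Between the sexes in KO-labelled libraries, the interferon response list was called upward in females at the preset correlation only. The median was 0.39 with 47 of 49 positive (Ifit2 0.72, Cmpk2 1.31, adjusted p = 3.0e-14, and adjusted p = 0.882 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.15 (Rps21 -0.66, Rpl3l -2.72, adjusted p = 0.00465, and adjusted p = 0.882 with an estimated correlation). The ribosomal list turned upward without the 4 libraries that went against their titled sex (adjusted p = 0.0388). It lost its call with the GC and length trend removed (0.256), without KO female 2 or KO male 2 (0.0878 and 0.140), and without KO male 1, where its direction was upward (0.476). No other list was called, but 8 were called without KO male 3 and 4 without KO female 1. With edgeR 0 genes passed, 722 had an unadjusted p under 0.05, 0 passed with DESeq2 or with limma voom and quality weights, and 324 passed without KO male 2. Xist had a log2 fold change of -1.12 and the Y-linked Eif2s3y of 0.12 (adjusted p = 0.922 and 0.996), with 3 of the 6 libraries opposite to their titles.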

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

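Tests of sex-linked transcripts, Esr2 counts, B-cell genes, the GC and length trend and dilution were chosen only after the results were seen, and the splits of the libraries and the test around Esr2 were planned.

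The interaction, a test of the difference in KO effect between the labelled sexes, called 9 lists at the preset correlation. With an estimated correlation none was called (adjusted p from 0.418 to 0.523), and fry called 0. Median differences on the log2 scale, female minus male, were 0.914 for interferon response, 0.485 for immediate early and heat shock, 0.326 for nuclear respiratory chain and 0.325 for cytosolic ribosomal protein genes. They were -0.570 for cell cycle, -0.537 for gut homing, -0.808 for dendritic cell, -1.08 for macrophage and monocyte and -1.25 for B-cell genes. Without the 4 libraries that went against their titled sex, the macrophage, dendritic cell and gut homing lists lost their call, and the other 6 kept it in the same direction. There KO male 3 alone stood for KO males, and it had the lowest mean correlation with the other libraries, 0.928. Calls kept or lost in that setting thus rest on that library.

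Sex-linked transcripts went against the title in WT female 2, KO female 1, KO male 1 and KO male 2. Cells of the other sex mixed into the sample were argued against, since these libraries kept at most 0.426% of the transcripts of their titled sex. Reads shared between X and Y paralogs were also argued against, with 0 Y-linked counts in the libraries with Xist beside at least 5141 counts of the X paralogs. Exchanged or wrong labels would give the whole pattern of the other sex, and 3 of the 4 libraries had it. KO male 1 missed only the upper limit of a range set after the data were seen. Its Xist was at 312 CPM, against 60.4 to 118 CPM in libraries that went with a female title. With 0 Y-linked counts, it too lacked the transcripts of its titled sex. Wrong labels stay open by that range only through KO male 1, whose sex-linked counts do not speak for its title. With at most 0.426% of the transcripts of the titled sex kept, the counts of all 4 libraries argue against their titled sex. No biological explanation was tested.

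Esr2 counts did not follow the titled genotype. A difference in depth was argued against, since total counts differed by 1.64 times and Esr2 counts by 6.71 times across the gap. Exchanged or wrong labels may account for it: 4 libraries of each titled genotype lay on the side of the gap opposite to the title, if the KO allele leaves few counts. On that condition, only WT female 3 went with its title in both Esr2 and sex-linked transcripts. Low and high Esr2 each occurred in 3 libraries with and 3 without Y-linked counts. Chance alone gives that arrangement in 43.3% of cases, so it decides nothing. A disrupted allele that is still transcribed was not tested. It could leave counts in KO-labelled libraries but would not lower them in WT-labelled ones. WT male 1, 2 and 3 held 0, 1 and 14 Esr2 counts and WT female 1 held 0, against 133 and 159 in WT female 2 and 3. Those values argue against such an allele as the whole account. For the 206 genes called between KO and WT averaged over the sexes, 1 of 100 splits drawn from 200 possible ones, the real one, gave as many. The highest other gave 2, so chance is argued against. The titled groups thus parted the libraries, but the splits cannot tell whether genotype or another difference between those groups did so.

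For the 206 genes, B cells among the sorted cells may account for part of the higher genes, with 18 of 19 B-cell genes higher adjusted over the list alone, although the CD4 gate would remove B cells: the most abundant, Cd74, averaged 772 ± 292 CPM in KO and 315 ± 174 CPM in WT, 4 of the 19 genes stand in another list and 9 had at least 1 CPM in every WT library. T cell receptor signalling genes had a median of 0.036 and a lower quartile of -0.20, against a median of -0.60 for the lower genes. Dilution by cells that are not T cells was thus argued against for the lower genes. Dilution by other T cells need not lower T cell receptor genes, so it stays open, and genes of resting T cells had a median of 0.29. For the higher genes, the GC and length trend was argued against as the whole cause, with 97.1% of their median change left (from 1.45 to 1.41, median SE 0.30 before and after). Only 23 of those 83 genes were still called, as the largest unadjusted p that passed fell from 0.000748 to 0.000122, and 58 of the 83 stayed under the first value. For the lower genes that trend stays open, with 70.4% left (from -0.60 to -0.42, median SE 0.12 and 0.11) and 11 of 123 called, while 38 of the 123 stayed under the first value, so both the lower limit and smaller changes took calls away. Title codes run in the same order as genotype, so a batch and the titled genotype cannot be told apart, an effect of the genotype itself stays untested, and the odds ratio of 0.447 within 10 Mb of Esr2 decides nothing on a carried segment while the titles do not part Esr2.

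In males the splits were too few for a share under 0.05, and 2 of 10 gave as many genes (real 10, highest other 26). Where the real count was 0, every split had to give as many, so the splits decide nothing: 10 of 10 in females (highest other 0), 10 of 10 for female minus male in WT (highest other 0), 10 of 10 in KO (highest other 2220) and 100 of 100 for the interaction (highest other 206, in a split that exchanged KO and WT in 1 titled sex). The split with 2220 set KO male 1, KO male 3 and KO female 2, the libraries that correlated least with the others, against the rest, which points to a structure of the samples.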

How the results depend on the processing

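Removal of the GC and length trend, of the 4 libraries against their titled sex and of the 3 libraries that correlated least, and limma trend on the log2 values, were chosen only after the data were seen. Scaling by relative log expression, a filter at 1 CPM, non-robust dispersion and limma trend left all 6 counts of called genes within 1.5 times. All 37 calls of named genes kept their direction in every setting that tested them. With the title number as a block 7 of the 37 remained called, with WT male 2 and 3 summed 12, without the 4 libraries 10, and with DESeq2 37. Except where a value is explained here, the cause was not tested.

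For KO minus WT averaged over the sexes, 206 genes became 605 with DESeq2, 597 with limma voom and quality weights, 627 with no filter on low counts, 9 with the title number as a block, 31 with WT male 2 and 3 summed, 34 with the GC and length trend removed, 14 without the 4 libraries and 1126 without the 3 libraries. In males, 10 genes became 403 with DESeq2, 0 with limma voom, 443 with no filter, 24 with only the groups compared, 0 with the title number as a block, 0 with WT male 2 and 3 summed, 6 without genes on X and Y, 135 without the 4 libraries and 0 without the 3. In females, 0 genes became 19 with DESeq2, 1698 with limma voom, 132 with no filter and 60 without the 3 libraries. For female minus male in WT, 0 genes became 33 with DESeq2, 348 with limma voom, 191 with no filter and 5 without the 4 libraries. In KO, 0 became 63 with no filter and 5 without the 4 libraries, and for the interaction 0 became 106 with no filter and 1 with DESeq2.

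Leaving out 1 library at a time gave 12 to 543 genes for the average, 0 to 734 in males, 0 to 2 in females, 0 to 38 for female minus male in WT, 0 to 324 in KO and 0 to 4 for the interaction. Without the 4 libraries, KO male keeps a single library, KO male 3, which is assumed to vary like the other groups. The 3 libraries were KO male 1, KO male 3 and KO female 2, all labelled KO. Without them KO male keeps only KO male 2, under the same assumption, so their removal did not treat the groups alike. Without the 4 libraries, the value of Eif2s3y, female minus male in KO, turned to a fitted -12.96, which is no bound, since the KO female libraries left had 0 counts. Against 3 counts over them it was at least 566-fold lower.

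With an estimated correlation 0 lists were called in each of the 6 comparisons. With fry 2 were called in males, 8 for the average and 0 in females, for female minus male in WT, in KO and for the interaction. With the GC and length trend removed, 1 list was called for female minus male in KO, and without the 4 libraries the ribosomal list turned upward there (adjusted p = 0.0388). Leaving out 1 library gave 10 to 16 lists in females, 11 to 13 in males, 10 to 14 for the average and in WT between the sexes, 2 to 8 in KO and 7 to 14 for the interaction. The agreement of the KO effect between the sexes (Pearson's r across genes, 0.266) was 0.350 for genes of at least 5 CPM, -0.016 without the 4 libraries, 0.046 without the 3 libraries and 0.150 to 0.297 without 1 library. The odds ratio around Esr2 was 1.05 at 5 Mb and 1.07 at 20 Mb. Depth limits genes with few counts: 3 counts were 0.291 CPM in the shallowest library.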

Other observations

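Among abundant transcripts that mark T cells, Cd4 averaged 631 ± 87.0 CPM in the KO-labelled and 584 ± 68.9 CPM in the WT-labelled libraries, and Cd3e 1138 ± 104 and 821 ± 131 CPM (SD, n = 6 each). The first and the second principal component held 28.6% and 20.1% of the variance between libraries. On the first, KO male 1, KO male 3 and KO female 2 lay at -35.2, -29.8 and -13.0. KO male 2, KO female 1 and KO female 3 lay at 16.2, 13.7 and 15.1, and the WT-labelled libraries between, from -8.49 to 13.2. The first component thus parted KO-labelled libraries from each other, across the titled sexes. KO male 3 had the lowest mean correlation with the other libraries, 0.928, followed by KO male 1 with 0.942 and KO female 2 with 0.944.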
